A study of Homo sapiens with 6 samples.

How the data were processed

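Messenger RNA was measured in 6 cultures of macrophages made from the THP-1 line, 3 given SCAFs and 3 given inert beads, each for 20 h at 300000 particles. Per the labels' protocols, the libraries were stranded, poly(A)-selected and made from 300 ng of RNA with 12 PCR cycles. The deposited unit is raw counts per Ensembl gene, 1 column per library, which held whole numbers only. The submitters' processing notes name STAR 2.7.10b and the GRCh38 build, without role or order. The program that counted reads, its strand setting and its annotation are not given in the sources used here, so reads of genes with overlapping exons, or with near-identical copies, may be assigned to either. Whether the 3 replicates of a group are separate experiments is not given in the sources used here either. Replicates were not pooled.

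Of the 28985 genes in the table, 99.3% matched a reference table of gene names, 198 did not, and 6490 had an ID in place of a name. Positions come from GENCODE 29 on GRCh38. No gene had a total of 0. Totals ranged from 31259170 to 41167493 counts per library, and the 10 most abundant genes took 9.88% to 11% of the counts. The counts have no molecular identifiers, so intervals and floors cover counting error only. For a gene with no count in any Beads library, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in Beads, the ratio is given with an exact 95% counting interval. No 2 libraries were copies of each other: counts of pairs differed with a chi-square of 30.05 to 193.1 per gene, where resequencing of 1 library would give about 1.

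The groups were compared in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, filterByExpr filter, TMM factors, 4 residual degrees of freedom). The filter kept 15671 genes with 99.93% of the counts. The p-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05. SE of a fold change was derived from the test's F. The batch was not in this model. Since the labels give the same 3 batches to both groups, the numbers pair the libraries, and the same test with batch as a block (2 residual degrees of freedom) was the first alternative. The deviations of same-batch libraries from their group means correlated at 0.634, 0.0993 and 0.536 over genes, and libraries of different batches at -0.589 to 0.149. The biological coefficient of variation was 0.240 without and 0.111 with the block. Blocked values stand beside a result where they change its call or move a count by more than 1.5 times.

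Gene lists (46, of which 45 had at least 5 tested members) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 45. Camera was repeated with an estimated correlation, and fry, which tests a list without comparing it with other genes, was run as well. With an estimated correlation camera rests on the few residual degrees of freedom of the fit, so it has little power, least with the block. For each list, members past the edgeR test over all genes and members past it adjusted over the list alone were counted. The lists, the tests, the thresholds, the rule for named genes and most alternatives were set before the data were examined. That rule names, per direction, the 12 genes with the largest change among those past the threshold with a mean of at least 5 CPM and 1 direction in all 3 batches. It adds up to 4 members of each list that passed or had at least 3 members past the test, up to 2 of any other list, and a fixed set of cytokine, macrophage, lipid, protease, collagen and keratin genes whatever their values, of which not all are given. The ninth lower gene past the threshold, the noncoding RNA ENSG00000277738, has no name in the reference table and a mean of 0.370 CPM, and the rule left it out. LPL was named by the same rule applied to the blocked fit.

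Alternatives were other scaling (RLE, upper quartile, total counts only), no filter and a stricter filter (5 CPM in at least 3 libraries), libraries thinned to the smallest total, mitochondrial genes left out, each library and each batch left out, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, and a test against a fold of 1.5. The closing section gives their effect. Exons of 202 named genes were compared with those of other genes, and 59 overlapped another gene's exons.

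The edgeR and camera steps were tested on simulated counts drawn from the real genes' means, the real library sizes and their batch structure (10 simulations, 15274 to 15297 genes tested). The changed genes were drawn from well-counted genes only, so the recovery of scarce genes is not covered. For SCAFs against Beads without the block, 0.800%, 33.6%, 86.6% and 96.0% of genes changed 1.5-, 2-, 4- and 8-fold were recovered, with 0% of calls false. With the block these shares were 69.0%, 91.4%, 100% and 100%, with 11% of calls false. Camera called the shifted list in 10 of 10 simulations and 0 of 450 unchanged lists in either fit. Counts were drawn independently for each gene and the unchanged lists at random. These list results therefore do not cover correlation between the members of a real list.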

Results

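Poly(A)-selected messenger RNA was sequenced in THP-1 cells, a human monocytic leukaemia line, that had been turned into macrophages with the phorbol ester PMA (200 nM for 24 h) and then rested for 24 h. These resting M0 macrophages spent 20 h with 300000 particles per culture. The particles were inert beads in the control group and Senescent-Cell Adhesion Fragments (SCAFs), debris of senescent cells, in the other. The type of cell that gave the SCAFs is not given in the sources used here. Each group held 3 libraries, and batch 1, 2 and 3 each held 1 library of either group. SCAFs replicate 3 carried another protocol number than the other 5 libraries. The deposited values are raw counts for 28985 genes. Library totals were 31844859, 31259170 and 39494981 counts in Beads replicates 1, 2 and 3, and 38828264, 41167493 and 34933232 in SCAFs replicates 1, 2 and 3. Levels are normalised read counts on the CPM scale (library totals adjusted by TMM), as mean ± SD over 3 libraries. Fold changes are SCAFs over Beads, on the log2 scale.

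The comparison asks which genes and pathways are higher or lower in macrophage cultures given SCAFs rather than inert beads. The counts do not part messages of the macrophages from RNA carried in with the SCAFs. Of 30 fibroblast and stromal markers tested, 15 were higher in SCAFs, and several of these were near 0 in Beads. The lists of senescence secretory factors, plasminogen and coagulation genes and TGF-beta targets also ranked higher by camera, with 6 of 31, 3 of 15 and 4 of 20 members past the test. These 3 list calls and that of the fibroblast list were not kept with the block and an estimated correlation (camera adjusted p = 0.308). That setting rests on 2 residual degrees of freedom and called no list at all. It has little power, so it can neither uphold nor refute these calls. Most cytokine genes were higher within each batch, and several of them differed more between batches than between groups. The glucose transporters SLC2A1 and SLC2A3 were higher within each batch, and CD36, FABP4 and LPL were lower within each batch, all 5 past the test only with batch as a block.

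Of 15671 genes tested, 123 were higher and 9 lower in SCAFs at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 1202 had an unadjusted p under 0.05. Each of the 123 and of the 9 moved in its direction in all 3 batches. With batch as a block, edgeR called 636 higher and 507 lower, including the same 123 and 9. In simulated data 11% of the calls were false with the block and 0% without it. The simulated changes were in well-counted genes drawn independently, so these shares need not hold for the real calls. Of the 636, 306 rose at least 2-fold, and of the 507, 68 fell at least 2-fold. The median fold change of all genes tested was 0.00 on the log2 scale. The counts moved with single libraries. Without Beads replicates 1, 2 and 3 in turn, 105, 37 and 56 genes were higher and 8, 0 and 2 lower. Without SCAFs replicates 1, 2 and 3 in turn, 36, 23 and 47 were higher and 0, 0 and 2 lower. Where edgeR called 0 lower, without Beads replicate 2 or SCAFs replicate 1 or 2, 238, 284 and 359 genes were lower at an unadjusted p under 0.05. With 16247, 15990 and 15979 genes tested, that is below what p-values with no true change would give on average in 1 direction. With the block and batch 1, 2 or 3 left out, 493, 176 and 1175 were higher and 239, 91 and 1128 lower. Of the 123 higher genes, 88 (71.5%) had a mean under 1 CPM in Beads, against 17.4% of all genes tested, and 36 had no count in any Beads library.

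The 12 largest rises included the collagen chains COL1A2, COL6A3 and COL1A1. COL1A2, a fibrillar collagen chain (ENSG00000164692, GRCh38 chromosome 7, 94394561 to 94431232), went from 0.0108 ± 0.0186 to 48.0 ± 8.42 CPM (SD, n = 3), from 1 count over the 3 Beads libraries. The ratio was 4920 with a 95% counting interval of 882 to 194000 (edgeR adjusted p = 0.000176). UCHL1, a deubiquitinase (ENSG00000154277, chromosome 4, 41256413 to 41268455), had no count in Beads and 11.5 ± 4.26 CPM in SCAFs, which is at least 394-fold higher (edgeR adjusted p = 0.00814). PXDN, a matrix peroxidase (ENSG00000130508, chromosome 2, 1631887 to 1744852), was also at 0 in Beads and at 11.1 ± 0.780 CPM in SCAFs, at least 380-fold higher (edgeR adjusted p = 0.00124). FLNC, a muscle-type filamin (ENSG00000128591, chromosome 7, 128830377 to 128859274), rose from 0.247 ± 0.102 to 44.5 ± 6.13 CPM, a log2 fold change of 7.44 (SE 0.28, edgeR adjusted p = 0.000176). SERPINB2, an inhibitor of plasminogen activation (ENSG00000197632, chromosome 18, 63871692 to 63903890), rose by 6.51 (SE 0.42, edgeR adjusted p = 0.00163) to 23.1 ± 6.98 CPM. COL6A3 (ENSG00000163359, chromosome 2, 237324003 to 237414375) rose by 4.59 (SE 0.30) to 50.2 ± 6.24 CPM, and COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632) by 4.26 (SE 0.24) to 36.9 ± 5.89 CPM. The other five largest rises were in TNC (8.20), LOXL2 (5.72), STC1 (5.27), INHBA (4.92) and GREM1 (4.91). COL1A2, PXDN, FLNC, SERPINB2, LOXL2, INHBA, COL6A3 and COL1A1 stayed past the edgeR threshold without any single library. UCHL1 did not without SCAFs replicate 2 (adjusted p = 0.0848), nor TNC (highest adjusted p = 0.0750) and STC1 (0.0752) without Beads replicate 2 or SCAFs replicate 2, and GREM1 passed only without Beads replicate 1 (highest 0.0919). Exons of LOXL2 overlap those of ENTPD4 on the same strand, at a mean of 42.8 CPM.

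**Figure D1:**
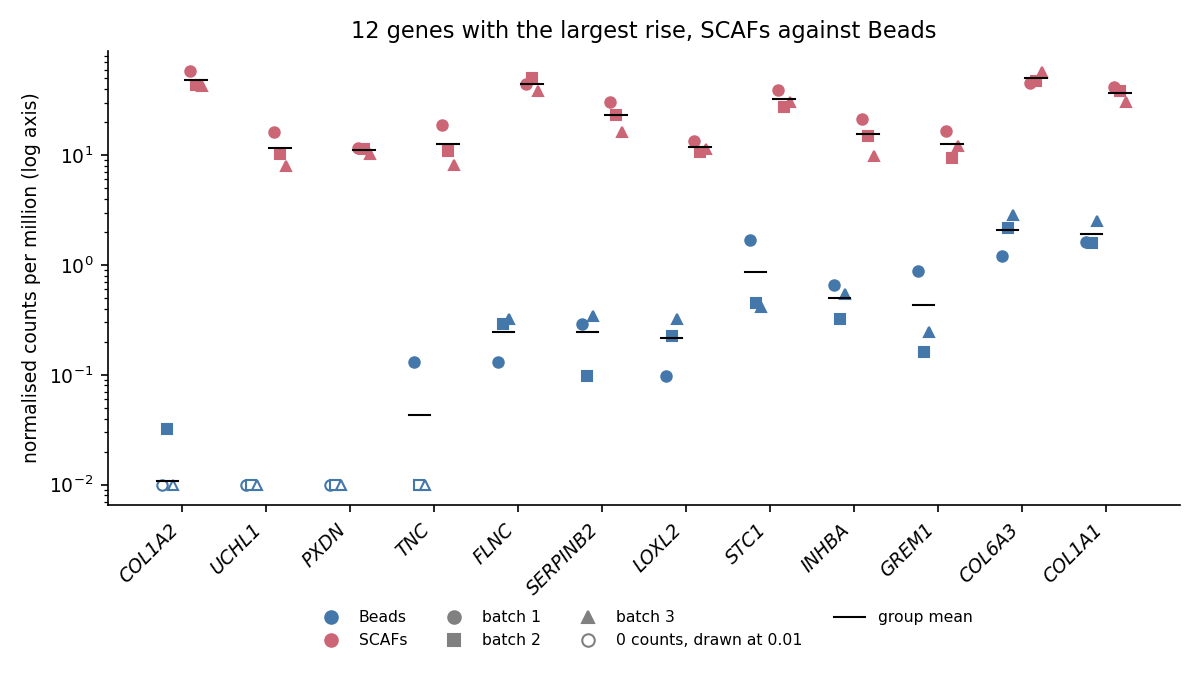
CPM (log axis) of the 12 genes with the largest rise, with 1 symbol per library (colour for the group, shape for the batch) and a line at each group mean. Open symbols are libraries with 0 counts, drawn at 0.01, and in all 12 genes every SCAFs library lies above every Beads library.

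The falls were smaller. BLVRB, biliverdin reductase B (ENSG00000090013, chromosome 19, 40447765 to 40465840), fell by 1.14 on the log2 scale (SE 0.13, edgeR adjusted p = 0.0168), from 85.9 ± 8.15 to 38.9 ± 5.03 CPM. LRRC4, a leucine-rich repeat adhesion protein (ENSG00000128594, chromosome 7, 128027071 to 128032107), fell by 1.06 (SE 0.11, edgeR adjusted p = 0.0124), from 100.9 ± 9.09 to 48.5 ± 3.90 CPM. PDGFRL (-1.23), SIGLEC11 (-1.05), ABCC6 (-0.89), SHMT1 (-0.86), ITSN1 (-0.70) and TKTL1 (-0.64) also passed. None of these 8 falls passed in every omission of a single library. BLVRB and LRRC4 were lost without Beads replicate 2, SCAFs replicate 1 or SCAFs replicate 2 (highest edgeR adjusted p = 0.111 for each). SIGLEC11 and SHMT1 passed only without Beads replicate 1, and ABCC6, PDGFRL, ITSN1 and TKTL1 in no such omission (highest adjusted p = 0.242, TKTL1). PDGFRL, SIGLEC11, SHMT1, ITSN1 and TKTL1 also missed the threshold when libraries were scaled by total counts only. With genes under 1 CPM in Beads left out of the test, 0 genes were called lower. Exons of PDGFRL and SHMT1 overlap those of MTUS1 (75.1 CPM) and SMCR8 (64.1 CPM) on the opposite strand, and the strand setting of the counting is not given in the sources used here.

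Fibroblast and stromal markers moved most among the 45 gene lists tested. Of 30 tested members 15 were higher, 22 when adjusted over the list alone, and 23 with the block. Their median log2 fold change was 2.57, also with members at 0 in Beads set at their bound (camera adjusted p = 6.51e-128, and adjusted p = 0.00648 with an estimated correlation, 0.308 with that and the block). IGFBP5 rose from 9.63 ± 3.68 to 159.5 ± 24.1 CPM, by 4.05 (SE 0.30, edgeR adjusted p = 0.00302). TAGLN rose by 4.05 (SE 0.20) and SPARC by 3.16 (SE 0.17), and these 3 genes passed without any single library. Exons of TAGLN overlap those of PCSK7 (48.4 CPM) on the opposite strand. COL3A1 rose from 1.78 ± 0.676 to 5.64 ± 1.34 CPM and passed only with the block (edgeR adjusted p = 0.131 without, 0.00230 with it). The epithelial list was higher too (camera adjusted p = 0.00585, and adjusted p = 0.459 with an estimated correlation), with a median of 0.13. Of its 12 members 0 passed edgeR (5 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom), 4 when adjusted over the list alone, and 4 with the block. Its camera call was lost without Beads replicate 1 (adjusted p = 0.0519) or SCAFs replicate 3 (0.0586). Its members were scarce, for example KRT18 at 1.65 ± 0.532 CPM in SCAFs (edgeR adjusted p = 0.389, and 0.0181 with the block, lost with batch 1 or 2 left out at 0.0529 and 0.104). KRT8 passed neither fit (0.388 and 0.161), and the exons of KRT8 and KRT18 overlap. Endothelial markers (median -0.35, camera adjusted p = 0.286) and lymphocyte markers (0.14, camera adjusted p = 0.398) did not pass, and neither did monocyte and macrophage identity genes (-0.14, camera adjusted p = 0.286).

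Senescence-associated secretory factors were higher (median 1.27, camera adjusted p = 5.06e-31, and adjusted p = 0.0290 with an estimated correlation, 0.308 with that and the block). Of 31 members 6 were higher, 15 when adjusted over the list alone, and 22 with the block. They included IGFBP5, INHBA (an activin subunit), STC1 and the protease MMP3, which rose from 0.249 ± 0.209 to 6.11 ± 2.54 CPM, by 4.64 (SE 0.59, edgeR adjusted p = 0.0242). The plasminogen and coagulation list had a median of 0.96 (camera adjusted p = 1.54e-20, and adjusted p = 0.0431 with an estimated correlation, 0.308 with that and the block). Of its 15 members 3 were higher, 8 when adjusted over the list alone, and 9 with the block. The plasminogen activator PLAT rose from 0.128 ± 0.166 to 7.18 ± 2.41 CPM, by 5.64 (SE 0.70, edgeR adjusted p = 0.0211). TGF-beta and SMAD targets had a median of 0.41 (camera adjusted p = 1.02e-13, and adjusted p = 0.0240 with an estimated correlation, 0.308 with that and the block), with 4 of 20 members higher, 8 when adjusted over the list alone, and 10 higher and 2 lower with the block. PMEPA1 rose by 2.78 (SE 0.35) and LTBP1 by 2.28 (SE 0.36). Several of these calls depended on single libraries. MMP3 and PMEPA1 were lost without Beads replicate 2 or 3 or SCAFs replicate 1 or 2 (highest edgeR adjusted p = 0.144 and 0.138), and PLAT without Beads replicate 2 or SCAFs replicate 1 or 2 (0.139). LTBP1 passed only without Beads replicate 1 (highest 0.218). All 9 senescence members under 1 CPM in Beads were called higher with the block. So were 2 of 2 such members in the plasminogen list and 2 of 2 in the TGF-beta list. Of all 2725 genes tested with a mean under 1 CPM in Beads, 187 were. Members near 0 in Beads pass the filter mainly through their SCAFs level, so these member counts are no separate support. Whether the macrophages made the messages of these 3 lists or the SCAFs carried them in was not tested.

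Matrix metalloproteinases and their inhibitors had a median of 0.25 (camera adjusted p = 0.00669, and adjusted p = 0.378 with an estimated correlation). The camera call was lost without SCAFs replicate 3 (adjusted p = 0.0987), under a stricter filter on low counts (0.470) and with genes under 1 CPM in Beads left out (0.178). Of 22 members 1 was higher, MMP3, with 2 when adjusted over the list alone and 5 with the block. The collagenase MMP1 went from 42.4 ± 20.9 to 267.1 ± 294.0 CPM, and the library of SCAFs replicate 3 alone held 606.0 CPM. MMP1 and the elastase MMP12 were higher in all 3 batches and passed only with the block (edgeR adjusted p = 0.0321 and 0.0271, against 0.435 and 0.603 without it), MMP1 not with batch 2 left out (0.0528). MMP9, at 2214 ± 2370 CPM in Beads and 2610 ± 2100 CPM in SCAFs, was also higher in all 3 batches and passed neither fit (edgeR adjusted p = 0.978, and 0.254 with the block).

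Inflammatory cytokines and chemokines were higher as a list (median 0.91, camera adjusted p = 2.18e-05, but adjusted p = 0.767 with an estimated correlation). Of 20 members 0 passed edgeR without the block (5 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom), 3 passed when adjusted over the list alone, and 13 passed with the block. Without the block, 16 of the 20 were higher in all 3 batches, against 22.2% of all genes tested. IL1B differed more between batches than between groups. It read 1037, 267.6 and 126.7 CPM in Beads replicates 1, 2 and 3 and 1566, 421.2 and 319.0 CPM in SCAFs replicates 1, 2 and 3, a log2 fold change of 0.69 (SE 0.87, edgeR adjusted p = 0.919). With the block IL1B rose by 0.86 (SE 0.14, edgeR adjusted p = 0.00882, and 0.0629 with batch 2 left out). CXCL8 likewise passed only with the block (edgeR adjusted p = 0.930 and 0.0449), and not with batch 2 left out (0.200). CCL2 went from 1.90 ± 1.28 to 5.44 ± 3.75 CPM and passed only with the block (edgeR adjusted p = 0.629 and 0.00232). IL6 had no count in Beads and read 7.55, 3.46 and 0.889 CPM in SCAFs replicates 1, 2 and 3 (edgeR adjusted p = 0.123, and 0.000821 with the block). CSF2 was at 0 in Beads too and read 3.14, 1.96 and 0.278 CPM in SCAFs replicates 1, 2 and 3 (0.200 and 0.00289), and LIF rose by 3.96 (SE 0.40) with the block (0.152 and 0.00135). TNF passed neither edgeR fit (adjusted p = 0.911 and 0.163).

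**Figure D2:**
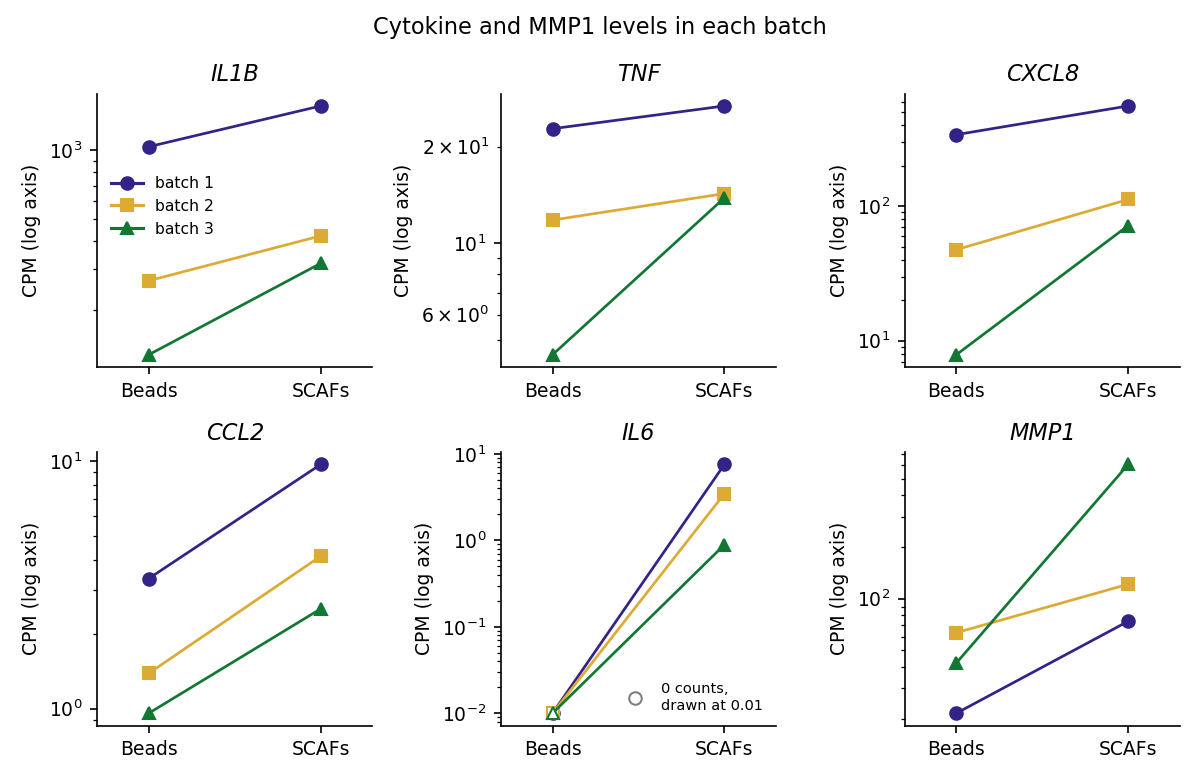
CPM (log axis) of 5 cytokine genes and MMP1 in Beads and SCAFs, with 1 line per batch and open symbols for 0 counts, drawn at 0.01. All 6 genes were higher in SCAFs in each of the 3 batches, and the largest MMP1 value was 606.0 CPM in batch 3.

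NF-kappaB pathway genes had a median of 0.33 (camera adjusted p = 0.00616, but adjusted p = 0.784 with an estimated correlation). The camera call was lost without Beads replicate 3 (adjusted p = 0.519) or SCAFs replicate 1 (0.288). Of 22 members 0 passed edgeR without the block, also when adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2 or by limma-voom. With the block 7 passed, among them the co-activator BCL3 (edgeR adjusted p = 0.679 and 0.0209, and 0.160 with batch 2 left out). S100 and alarmin genes had a median of 0.34 (camera adjusted p = 0.0288, but adjusted p = 0.342 with an estimated correlation), with 0 of 9 members past edgeR without the block, also when adjusted over the list alone, by DESeq2 or by limma-voom (2 at an unadjusted p under 0.05). With the block 4 passed, such as S100A10 (edgeR adjusted p = 0.699 and 0.00530). The S100 call was lost under a stricter filter on low counts (camera adjusted p = 0.122).

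Hypoxia response genes had a median of 0.38 (camera adjusted p = 1.66e-06, but adjusted p = 0.315 with an estimated correlation). Of 20 members 1 was higher, 5 when adjusted over the list alone, and 7 with the block. That gene was LOX, a collagen crosslinker that is also in the fibroblast list (2.30, SE 0.32, edgeR adjusted p = 0.0329). LOX passed only without Beads replicate 3 among single-library omissions (highest adjusted p = 0.175), and its exons overlap those of SRFBP1 (14.7 CPM) on the opposite strand. Glycolysis genes had a median of 0.25 (camera adjusted p = 0.000559, but adjusted p = 0.676 with an estimated correlation). Of 21 members 0 passed edgeR (4 higher at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom), 2 when adjusted over the list alone, and 8 were higher and 1 lower with the block. The glucose transporter SLC2A1 went from 161.9 ± 25.7 to 288.4 ± 64.5 CPM (edgeR adjusted p = 0.200, and 0.000913 with the block), and SLC2A3 from 13.3 ± 5.24 to 27.1 ± 7.0 CPM (0.435 and 0.00133). Actin and focal adhesion genes had a median of 0.00 and a mean of 0.26 (camera adjusted p = 0.00305, but adjusted p = 0.676 with an estimated correlation). That call was lost without SCAFs replicate 2 (adjusted p = 0.0643) and on limma-voom values (0.0620). Of 28 members 2 were higher, 4 when adjusted over the list alone, and 5 with the block. These 2 were TAGLN and TPM2 (0.81, SE 0.10, edgeR adjusted p = 0.0184), both also fibroblast list members, and TPM2 missed the threshold in each omission of a single library (highest adjusted p = 0.133).

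Markers of SPP1-TREM2 lipid-associated macrophages were lower (median -0.19, camera adjusted p = 0.00616, but adjusted p = 0.244 with an estimated correlation). Of 18 members 0 passed edgeR (6 lower at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom), 3 were lower when adjusted over the list alone, and 7 were lower with the block. The fatty acid carrier FABP4 went from 584.0 ± 184.0 to 270.3 ± 96.7 CPM and decreased by 1.13 (SE 0.11) with the block (edgeR adjusted p = 0.414, and 0.00107 with the block). LIPA, a lysosomal lipase, went from 371.6 ± 62.5 to 224.3 ± 28.8 CPM (0.155 and 0.00198), and LPL, lipoprotein lipase, from 1136 ± 497.0 to 592.4 ± 218.0 CPM (0.629 and 0.00109). TREM2 passed only with the block (edgeR adjusted p = 0.0232) and not with batch 1 or 2 left out (0.0820 and 0.0696). SPP1 passed neither fit (0.936 and 0.514). The scavenger receptor CD36 went from 631.7 ± 146.0 to 316.6 ± 26.7 CPM (edgeR adjusted p = 0.0737, and 0.00145 with the block).

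Interferon-stimulated genes were slightly lower (median -0.14, camera adjusted p = 0.0372, but adjusted p = 0.774 with an estimated correlation). The call was lost without Beads replicate 1 (adjusted p = 0.426), Beads replicate 2 (0.126), SCAFs replicate 1 (0.0909) or SCAFs replicate 3 (0.0586), and under a stricter filter (0.0775). Of 35 members 0 passed edgeR, also when adjusted over the list alone, by DESeq2 or by limma-voom (4 lower at an unadjusted p under 0.05). With the block 2 were lower, USP18 (edgeR adjusted p = 0.00397) and RSAD2 (0.0358), neither of them with batch 2 left out (0.0666 and 0.206). IFIT1 (edgeR adjusted p = 0.911 and 0.696 with the block), ISG15 (0.956 and 0.736) and CXCL10 (0.975 and 0.994) passed neither fit. Proliferation genes were lower (median -0.15, camera adjusted p = 0.00616, but adjusted p = 0.784 with an estimated correlation), with 0 of 32 members past edgeR without or with the block, when adjusted over the list alone, by DESeq2 or by limma-voom (1 lower at an unadjusted p under 0.05 without the block). Their call was lost without Beads replicate 3 (adjusted p = 0.264) or SCAFs replicate 3 (0.363), and without both of these libraries the median was 0.03. MKI67 went from 194.9 to 149.2 CPM (edgeR adjusted p = 0.699 and 0.0848).

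**Figure D3:**
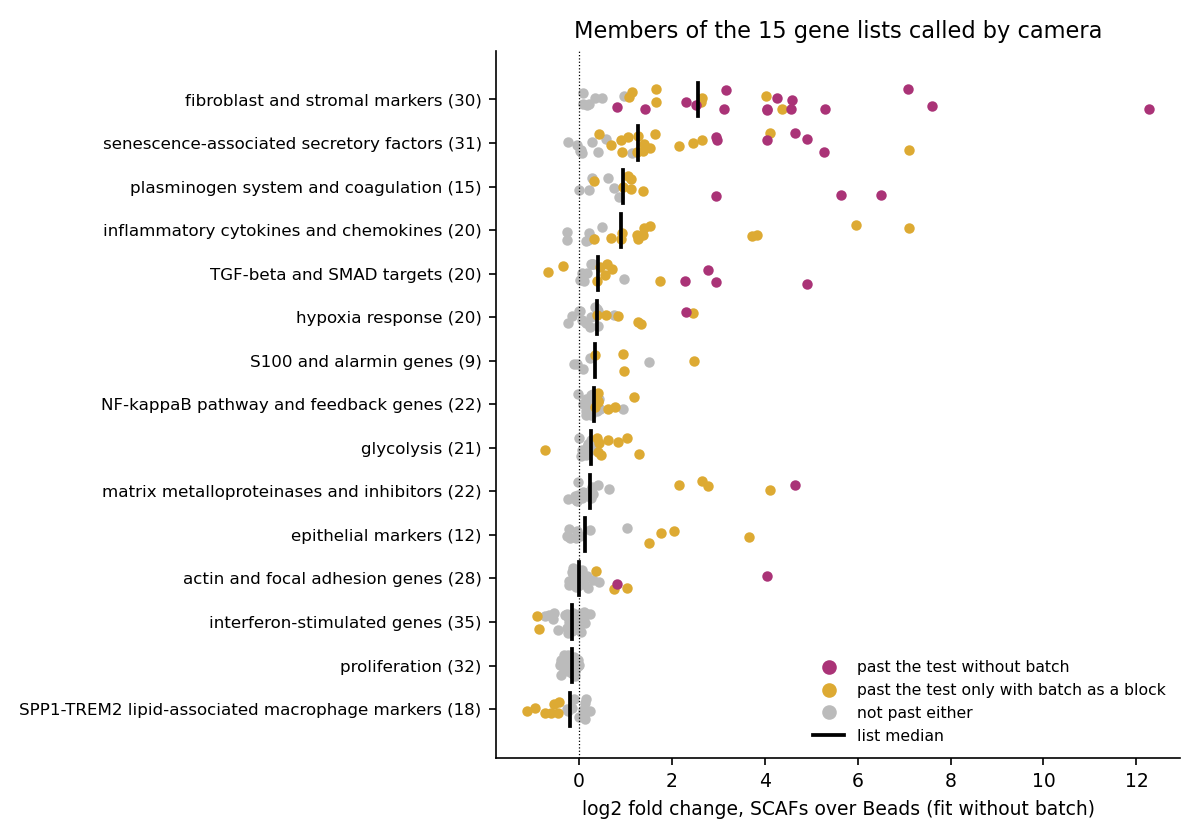
Log2 fold change (SCAFs over Beads, fit without batch) of each tested member of the 15 lists called by camera, with the number of members in brackets, colours for members past the test and a bar at the list median, and genes with 3 counts or fewer in Beads drawn at their bound or ratio. The medians run from 2.57 in the fibroblast and stromal list to -0.19 in the SPP1-TREM2 list.

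The other 30 lists did not pass camera without the block. With the block 4 of these did. Classical (M1-type) activation markers were higher (median 0.19, camera adjusted p = 0.176 and 0.00357 with the block), as were immediate early genes (0.42, 0.0580 and 0.0156, lost with batch 3 left out at 0.0989). Integrins and cell adhesion genes were higher (0.05, 0.0978 and 0.0494, lost with batch 2 or 3 left out at 0.0805 and 0.173). Cholesterol biosynthesis and uptake was lower (-0.12, 0.0525 and 0.0292, lost with batch 1 or 2 left out at 0.339 and 0.0828). With an estimated correlation none of these 4 blocked calls held (camera adjusted p = 0.356, 0.718, 0.718 and 0.806). That setting has little power at 2 residual degrees of freedom. Among the lists that passed camera in neither fit, alternative (M2-type) markers had a median of -0.37 (camera adjusted p = 0.240), phagocytosis and clearance receptors -0.02 (0.546), Fc and complement receptors -0.09 (0.240), complement components -0.04 (0.444) and lysosomal proteins -0.10 (0.140). The camera adjusted p was 0.601 for MHC class II, 0.518 for MHC class I, 0.556 for Toll-like and nucleic acid sensors, 0.815 for inflammasome genes, 0.952 for vacuolar ATPase subunits and 0.966 for autophagy genes. It was 0.966 for LXR targets, 0.873 for fatty acid synthesis, 0.852 for oxidative phosphorylation, 0.631 for NRF2 targets, 0.815 for iron handling and 0.883 for ATF4 targets. It was 0.966 for endoplasmic reticulum chaperones, 0.412 for the heat shock response and 0.966 for p53 targets. The lists that follow RNA handling did not pass either, with mitochondrially encoded messages at 0.440, cytosolic ribosomal proteins at 0.286 and replication-dependent histones at 0.815. In the complement, fatty acid synthesis, oxidative phosphorylation, NRF2, inflammasome and phagocytosis lists the median, the mean or the test differed in sign. The metallothionein list had 4 tested members and was not tested.

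With the block, 2 of 17 M2-type members were higher and 7 lower, among them the scavenger receptor MSR1 (-0.91, SE 0.10, edgeR adjusted p = 0.550 without and 0.00200 with the block). The phagocytosis list had 5 higher and 5 lower of 28, the Fc and complement receptors 0 and 4 of 13, the lysosomal list 2 and 5 of 33, the integrins 8 and 5 of 24 and the immediate early genes 7 and 1 of 22. The sensor list had 4 and 1 of 22, the NRF2 list 4 and 3 of 22 and the ATF4 list 4 and 0 of 22. The rest of the 30 lists had at most 3 members called in either direction. Without the block single members passed in some of these lists, and they were picked out after their values were seen. TGM2, a transglutaminase of the M2-type list, rose by 1.60 (SE 0.24, edgeR adjusted p = 0.0424), and the integrin chains ITGAV and ITGA2 by 0.76 and 1.34. CD163, MRC1, HMOX1, MERTK and CDKN1A passed neither edgeR fit (adjusted p without and with the block 0.994 and 0.855, 0.900 and 0.0817, 0.968 and 0.225, 0.992 and 0.959, 0.955 and 0.672). ABCA1 rose by 0.79 (SE 0.15) with the block (edgeR adjusted p = 0.360 and 0.0171, and 0.0512 with batch 1 left out).

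The gene lists carry a further limit. With an estimated correlation, camera called 4 of the 45 lists, the fibroblast, senescence, plasminogen and TGF-beta lists, against 15 with the preset correlation, and with the block it called 0 (smallest adjusted p = 0.308), against 19. At 2 residual degrees of freedom the blocked test with an estimated correlation had little power, so its 0 calls decide little. The fibroblast list stood at 0.308 there, at 2.31e-105 with the preset correlation, and fry still called it (adjusted p = 0.0348). The real split of the 6 libraries gave 15 lists, and the highest of the other splits into 3 and 3 gave 16. In simulated data with the batch differences of these libraries, edgeR without the block recovered 33.6% of genes changed 2-fold and 86.6% of those changed 4-fold. All of these simulated changes were in well-counted genes.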

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

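Most alternatives were set before the data were examined. Those that leave out genes under 1 CPM in Beads, that leave out a batch within the blocked fit, or that repeat the list tests within it were chosen after the data were seen. Of 123 higher and 9 lower genes, RLE factors gave 123 and 9, upper-quartile factors 115 and 8, libraries thinned to the smallest total 122 and 7, mitochondrial genes left out 123 and 9, and limma-voom 143 and 9. Total counts only gave 109 and 4, no filter 216 and 19, and the stricter filter 31 and 2, with fewer genes tested. DESeq2 called 279 and 52, an adjusted p under 0.01 left 31 and 0, and a test against a fold of 1.5 left 73 and 0. With genes under 1 CPM in Beads left out, which removes most of the higher genes, edgeR called 7 and 0 (433 lower at an unadjusted p under 0.05). Fewer genes tested would not by itself lower these counts. The omission took out 88 of the 123 higher genes, and the Benjamini-Hochberg adjustment depends on the ranks of all genes tested. How much of the loss this explains was not tested. Under the other scalings the median log2 fold change of all genes tested was -0.006 to 0.013.

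Adding the batch gave the largest rise in the number of genes called. With the batch pairing as a replicate block, edgeR called 636 higher and 507 lower, and DESeq2 655 and 499. With the block and genes under 1 CPM in Beads left out, 394 and 438 were called, and with the block and batch 1, 2 or 3 left out 493 and 239, 176 and 91, and 1175 and 1128. The blocked fit lowers the biological coefficient of variation from 0.240 to 0.111. In the simulated data, with changes in well-counted genes only, 11% of its calls were false, a share that need not hold for the real calls. Beyond the genes and lists reported as passing only with the block, the block changed no call of a gene or list that the report names.

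Leaving out 1 library, or both libraries of 1 replicate number, without the block, gave 0 to 105 higher genes and 0 to 8 lower genes, with fewer samples in each fit. The count of 0 higher came without replicate 2 (360 at an unadjusted p under 0.05). Counts of 0 lower came without Beads replicate 2, SCAFs replicate 1, SCAFs replicate 2, replicate 2 and replicate 3 (238, 284, 359, 124 and 495 lower at an unadjusted p under 0.05). Apart from the 495, these unadjusted counts and the 360 are below what p-values with no true change would give on average in 1 direction. The same omissions gave 11 to 16 higher lists and 2 to 7 lower lists, 7 without Beads replicate 3. Of the 22 higher genes that the rule for named genes picked, 11 passed without each single library, and of the 8 lower ones 0 did. Camera with an estimated correlation called 4 higher and 0 lower lists of the 12 and 3, and fry 5 and 1. Within the blocked fit the estimated correlation called 0 and 0 (smallest adjusted p = 0.308) and fry 3 higher lists and 1 lower. That lower list, Fc and complement receptors (fry adjusted p = 0.0348), is not among the lists camera called. The SPP1-TREM2 list lost its fry call with the block (0.0797). The senescence (0.0685), plasminogen (0.0746) and S100 (0.0653) lists lost theirs too. The median of the proliferation list ran from -0.291 without replicate 2 to 0.028 without replicate 3 and so reversed, and it was 0.030 with batch 3 left out and the replicate block, and the cause was not tested. Depth limits what was 0 in Beads: 36 of the higher genes have a lower bound on their fold only, and 52 had at most 3 counts in Beads.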

Other observations

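The tests of explanations, the counts over splits and the repeat of the rule for named genes on the blocked fit were chosen after the results they concern were seen, while the blocked fit and the omission of single libraries were planned. With the batch as a block, the rule for named genes gave the same 12 rises as without it and 12 other falls. ADRA2B, an adrenergic receptor, fell by 2.71 on the log2 scale (SE 0.19, edgeR adjusted p = 0.000269), and PDK4, a kinase that restrains pyruvate oxidation, fell by 1.79 (SE 0.18, adjusted p = 0.00139). BBOX1, an enzyme of carnitine synthesis, fell by 1.61. The short-chain fatty acid receptor FFAR2 (-1.37) and the selenium carrier SELENOP (-1.33) were also lower, and ZNF385B, TMEM37, GALNT16, PIGR, EDNRA, SLITRK5 and PLK2 changed by -1.71 to -1.35. None of these 12 passed without the block.

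Genes of fibroblasts and stroma were higher in SCAFs. A candidate explanation is RNA carried in with SCAFs of fibroblast-like cells, whose origin is not given in the sources used here. Of 11 fibroblast list members under 1 CPM in Beads, 10 were called higher with the block, against 3 of 14 in the epithelial, endothelial and lymphocyte lists (one-sided Fisher exact p = 0.000787). Of the 19 fibroblast members at 1 CPM or more in Beads, 13 were also called higher. These counts restate the pattern and would follow from transcription by the macrophages too, so they leave the explanation open. The most abundant members were COL6A1 and COL6A2, at 1650 and 844.0 CPM in Beads and 1866 and 975.5 CPM in SCAFs, neither of them called with the block (edgeR adjusted p = 0.312 and 0.290). Among the members that were called, IGFBP5 reached 159.5 CPM in SCAFs, TPM2 64.9 CPM, COL6A3 50.2 CPM, COL1A2 48.0 CPM and COL3A1 5.64 CPM. Transcription of these genes by the macrophages and carried RNA cannot be told apart. The highest SCAFs library exceeded the lowest by a median of 1.78 times in the 10 fibroblast members, against 7.24 times in 13 called inflammatory members, and a stable response to SCAFs could give the same ratio. The separate protocol number of SCAFs replicate 3 is argued against, since without that library the list's median was 2.58 (camera adjusted p = 3.15e-100).

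The inflammatory list was higher without the block by camera at the preset correlation, but its members passed edgeR over all genes only with the block. With an estimated correlation the list was called in neither fit (camera adjusted p = 0.767 without and 0.308 with the block). A candidate explanation is that the batches differed in their inflammatory state, which widened the spread. The SE without the block was 3.20 times that with it in the median of 20 inflammatory members, against 1.36 for all genes tested. This restates that the members pass only with the block, so it leaves the explanation open. Inflammatory messages carried in with the fibroblast messages in 1 fixed proportion are argued against for the 5 inflammatory members under 1 CPM in Beads. Their CPM added over Beads in batch 1 against batch 3 had a median log2 ratio of 3.09 (range 0.90 to 3.50), against 0.57 (range 0.32 to 1.97) in 10 fibroblast members under 1 CPM in Beads, a difference of 2.52 (permutation p = 0.00505). The permutation shuffled genes of the same libraries, which are not independent, so its p covers no spread between cultures. The argument rests on the medians, and the 2 ranges overlap. IL6 and CSF2 fell across SCAFs replicates 1 to 3 more steeply than COL1A2 did. For the 8 called members at 1 CPM or more in Beads the difference was 1.32, but the level in the macrophages themselves enters it, so the explanation stays open there. The members were parted by Beads level after a test over all of them together had been seen, and each ratio rests on 1 pair of libraries per batch. Batch 3 holds SCAFs replicate 3, the library with another protocol number. A difference particular to that library is therefore not excluded as a source of the gap. SCAFs that differed in composition between batches stay open, as does a response of the macrophages to SCAFs, which the design names and which was not tested apart.

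The block also called 507 lower genes. Dilution of macrophage RNA by RNA from the SCAFs would lower messages that the SCAFs lack, while messages present in both could stay level. Scaled by total counts only, the blocked median of all genes tested was 0.01 (quartiles -0.16 and 0.16). That of the lower genes was -0.52, and 6.46% of genes lay at or below it. The median of all genes includes messages that the SCAFs may also hold, so it cannot decide on dilution. With the block and TMM factors, the 20 monocyte and macrophage identity genes had a median of -0.13, with 2 higher and 3 lower. On that scaling the lower genes had a median of -0.53. The median of all genes tested was -0.003 with TMM factors and 0.01 with total counts only, so the scaling moved the genes little. Dilution that lowered all of the identity genes as far as the lower genes is argued against, and a weaker dilution stays open. The separate protocol number of SCAFs replicate 3 is argued against as well: with batch 3 left out 1128 genes were lower, including 497 of the 507. A lowering of these genes in the macrophages stays open, as a hypothesis.

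The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Without the block the real split called 132 genes and the highest of the others 0, as 1 of 10 splits reached the real count. It called 15 lists and the highest of the others 16, as 4 of 10 splits reached the real count. With the block, 4 splits put 1 library of each batch in each group, again too few. The real one called 1143 genes and the highest other 0, and 19 lists against 15, so 1 of 4 reached the real count in both. The other splits that reached 15 lists without the block each put both libraries of batch 1 in 1 group. Whether the batch raised their counts was not tested. The split of Beads replicate 1 with SCAFs replicates 2 and 3, which parts each batch, gave 12 lists without and 15 with the block. The blocked value for the real split is the 19 lists given here.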
